A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

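Total RNA from budding yeast was measured on single-colour NimbleGen expression arrays. The samples were cultures of a BY-series strain, a common laboratory background, that carried either wild-type RPB1 or 1 of 6 rpb1 mutant alleles. RPB1, named RPO21 in the gene table, encodes the largest subunit of RNA polymerase II. Per the labels, cells were grown in rich medium at 30 °C with shaking, RNA was extracted with hot acid phenol, and the target was labelled with biotinylated nucleotides. There were 14 arrays, 2 for each of 7 strains.

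The authors scanned the arrays and extracted 1 mean pixel intensity per spot with NimbleScan, versions 2.1.49 and 2.2.1e per the file headers. The deposited unnormalized values are perfect-match and mismatch probe intensities, with 16 probe pairs per gene in each of 2 printed blocks. The authors also made normalized probe intensities and 1 gene intensity per array by RMA with quantile normalization. In those normalized values the tails of the distribution were alike among arrays of one day and differed between days, so the arrays of each day may have been normalized apart. The perfect-match medians still differed within a day, from 119.14 to 398.49 on day A and from 151.62 to 253.39 on day B. The main values here were made from the unnormalized perfect-match intensities, and the authors' normalized values were used as alternatives. Perfect-match intensities were corrected for background by normexp with an offset of 50, quantile normalized over all 14 arrays, put on the log2 scale and summarised for each gene by median polish of its 32 spots with at most 20 iterations. This used R 4.3.3, limma 3.58.1, statmod 1.5.0 and version 1.17.8 of data.table. Gene values made in this way are relative to the other genes of an array, so a change of all transcripts together would not be seen. All 5867 genes on the array were tested, and 5847 of them matched the reference gene table (R64), which gave symbols, positions and lengths. The other 20 genes had no length. The length is the span of the gene from start to end on the chromosome, so it includes any introns, and is called coding length below. Of protein-coding lengths, 96.24% were multiples of 3.

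Depth for these arrays is signal over background, and the number of arrays limits the precision. Each array carried 10399 spots with random sequences. A gene was counted as above background on an array when the median of its 32 raw intensities passed percentile 95 of those random spots. Where one strain lay below background on both arrays and the other above, the change is given as a bound, written "at least". It sets the mean of the higher strain against, on each array of the lower strain, the larger of the gene's own value and the lowest value of any gene above background on that array. Where the gene's own value is the larger on both arrays, the bound equals the fitted fold. No fold is given where both strains were below background.

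Differences between strains were fitted with limma (lmFit, eBayes) on all 14 arrays, so that the 7 strains shared 1 estimate of the spread. The residual degrees of freedom were 7 and the prior degrees of freedom 3.57. Tests were two-sided, p was adjusted by Benjamini-Hochberg over the genes of 1 comparison, and the threshold was an adjusted p of 0.05. Values are log2 fold changes ± the standard error of the fit, with n = 2 arrays per strain. The wild-type replicates correlated least with each other (r = 0.943), followed by those of rpb1-E1230K (r = 0.960), so this shared spread may be too small for both strains. The ± and p of comparisons that include wild type or rpb1-E1230K may then be too small as well. The comparisons were each mutant with wild type, the mean of the 6 mutants with wild type, rpb1-D260N with rpb1-D261N, rpb1-N488D with rpb1-E1103G, a moderated F-test over the differences among the 6 mutants, and the count of genes changed one way in all 6. A trend of expression with coding length was tested by an exact two-sided permutation test over the 91 splits of the 14 arrays into 12 and 2. With 2 arrays against 2, an exact test of a single value cannot go below p = 0.33, so no such test is given for a single mutant. The fit of rpb1-D260N against wild type was tested on simulated data: of 100 genes given a log2 change of 1, 82 were recovered, of 100 given a log2 change of 2, 97 were recovered, and 7 unchanged genes were called. The simulation drew independent noise with the same spread in all strains, held no day effect and changed only these genes. It therefore does not show how well the calls hold where a strain varies more, as wild type did.

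Gene lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of 1 comparison. Lists needed at least 5 measured genes to be tested. Camera with a correlation estimated for each list, and fry, were run beside it. With an estimated correlation none of the 280 list tests against wild type passed, so every list call below rests on the preset correlation. Lists based on GC content and on introns were planned and not run, because the reference holds no genome sequence or exon table. The result of 1 further list is not reported here, and its tests are among the 280. Beside each count over all genes tested, the count adjusted over the list alone is given where it differs.

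Replicate 1 of each strain belonged to day A and replicate 2 to day B. Residuals of strains correlated within a day at over 0.1 in 16 of 21 pairs of strains, with a median of 0.16, so the day was fitted as a block in an alternative. Images were extracted in 3 sessions: session 1 held replicate 1 of wild type, rpb1-R320C, rpb1-N488D and rpb1-E1230K, session 2 held replicate 1 of the other 3 strains, and session 3 held all of day B. Session was fitted as a block in another alternative. Values within a day are differences between single arrays.

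The genes named are, for each mutant, the 8 largest changes each way among genes past the threshold whose mutant arrays both lay on one side of both wild-type arrays. For the mean of the 6 mutants they are the 10 largest each way with one sign in all 6, for each pair of mutants the 6 largest each way, for the F-test the 6 smallest p, and for each list up to 4 members with the smallest adjusted p. RPO21, IMD2, IMD3, IMD4, DST1, the auxotrophic markers and the mating-type genes are always considered. The text gives a selection of these. Groups, comparisons, tests, lists, the rule for named genes and the alternatives were chosen before the data were examined. Exceptions are marked as chosen after the data were seen. They are 3 lists (glucose-repressed genes, Ty elements, Y' helicases), the longest genes without Ty elements, the comparison of each mutant with the other 5, the test of days against each other, array weights, the authors' values with a block, and fits without doubted arrays. Other alternatives were no background correction, a normexp offset of 0, mismatch probes in the quantile normalization, median scaling, the mean in place of median polish, the authors' gene values and normalized probes, the dimmest 25% of genes left out, a variance trend with robust eBayes, only the strains compared, a block with the length trend removed, stricter thresholds, and each array left out in turn.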

Results

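Transcript levels of 5867 genes were measured in 7 yeast strains: wild-type RPB1 and the mutants rpb1-D260N, rpb1-D261N, rpb1-R320C, rpb1-N488D, rpb1-E1103G and rpb1-E1230K. Each strain had 2 arrays, 1 from day A and 1 from day B. The series concerns alleles of the largest RNA polymerase II subunit that make cells sensitive to 6-azauracil, a drug that lowers cellular GTP, but all cultures were grown in rich medium without a stated drug. The median perfect-match intensity stood 1.56 to 4.26 times above the median of the random control spots, lowest on rpb1-N488D replicate 1 and highest on rpb1-E1103G replicate 1. Between 1335 and 2691 genes per array were above background. Replicates correlated over genes at r = 0.994 in rpb1-D261N and at r = 0.943 in wild type. Wild type replicate 2 correlated better with rpb1-E1230K replicate 1 (r = 0.976) than with its own replicate. The first principal component held 66.2% of the variance.

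The mean of the 6 mutants was compared with wild type to ask what the mutant strains shared in rich medium. In this comparison the growth state of the wild-type cultures was not separated from an effect of the alleles. The same holds for each mutant against wild type. Genes for making ribosomes were higher in the mutants and genes of stress defence and respiration were lower. All 137 cytosolic ribosomal protein genes rose, with a median log2 change of 2.32, and all 75 ribosome biogenesis genes rose, with a median of 1.19. Examples are RPS9B at 3.22 ± 0.33 (adjusted p = 7.22e-05), RPL22A at 3.06 ± 0.33 (adjusted p = 8.28e-05) and the nucleolar methyltransferase gene NOP1, at least 8.94-fold higher (adjusted p = 0.000137). The wild-type arrays of RPS9B had an SD of 1.26, and its change was 4.02 on day A and 2.42 on day B. Of 41 general stress genes, 39 fell and 1 rose (40 and 1 adjusted over the list alone), with a median of -2.25. ALD3, a stress-induced aldehyde dehydrogenase, fell by 3.78 ± 0.37 (adjusted p = 6.18e-05), and FMP16, of the mitochondria, was at -4.18 ± 0.36 (adjusted p = 5.06e-05). The largest decreases also held SIP18, a desiccation response gene, at -4.52 ± 0.62, and JEN1, the lactate transporter, at -4.45 ± 0.61, which were each above background on only 1 of 12 mutant arrays. ALD3 and FMP16 were above it on 3 of 12 mutant arrays each, so background limits the size given for all 4 of these decreases.

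The camera adjusted p was 2.29e-38 for ribosomal proteins, 1.04e-18 for ribosome biogenesis and 1.18e-12 for general stress, each with an adjusted p = 0.475 with an estimated correlation. On day A the medians were 2.92, 0.98 and -1.99, and on day B they were 1.70, 1.44 and -2.90. All 31 respiratory chain genes fell (median -1.27, adjusted p = 9.34e-11, and adjusted p = 0.475 with an estimated correlation), with -1.73 on day A and -0.90 on day B. Among them CYT1, cytochrome c1, fell by 1.80 ± 0.19. Of 16 TCA cycle genes 15 fell (median -1.59, adjusted p = 9.18e-07, and adjusted p = 0.475 with an estimated correlation), with -1.99 on day A and -1.40 on day B. SDH1, a succinate dehydrogenase subunit, fell by 2.81 ± 0.32. Of 68 mitochondrial ribosomal protein genes 42 fell (45 adjusted over the list alone), for example MRPL4 at -0.97 ± 0.13 (above background on 4 of 12 mutant arrays), with a list median of -0.46 (adjusted p = 8.9e-07, and adjusted p = 0.577 with an estimated correlation), -0.51 on day A and -0.37 on day B. Of 26 heat shock genes 18 fell and 1 rose (19 and 2 adjusted over the list alone), with SSA4 at -3.12 ± 0.34 (above background on 4 of 12 mutant arrays) and a list median of -0.79 (adjusted p = 6.63e-05, and adjusted p = 0.475 with an estimated correlation), -1.05 on day A and -0.56 on day B. The wild-type cultures themselves differed between days: the median level of 10 glucose-repressed genes, a list chosen after the data were seen, was 12.51 on day A and 8.22 on day B, while the mutant arrays lay between 7.55 and 8.20.

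Nucleotide synthesis genes also rose. The guanylate list holds the IMP dehydrogenase genes IMD2, IMD3 and IMD4, whose product starts GTP synthesis, with GUA1 and GUK1. All 5 rose (median 2.44, adjusted p = 0.000304, and adjusted p = 0.475 with an estimated correlation), GUA1, GMP synthase, by 2.93 ± 0.26. IMD2 (YHR216W, R64 build, chromosome VIII, 554396 to 555967) was at 2.44 ± 0.30 (adjusted p = 0.000144), IMD3 at 2.30 ± 0.27, and IMD4 at least 7.37-fold higher. These genes are close copies, so their probes may share signal. Of 16 purine and one-carbon genes 15 rose and 1 fell (median 1.79, adjusted p = 3.9e-07, and adjusted p = 0.475 with an estimated correlation). ADE17, of the last steps to IMP, rose by 3.10 ± 0.48, and ADE57 by 2.62 ± 0.25. Of 11 pyrimidine genes 9 rose and 2 fell (median 0.86, adjusted p = 0.00372, and adjusted p = 0.475 with an estimated correlation). URA2, the first enzyme of the pathway, rose by 1.61 ± 0.14, while URA10, a minor copy of orotate phosphoribosyltransferase, fell by 2.80 ± 0.36 and was above background on 1 of 12 mutant arrays. The list of attenuated nucleotide genes holds 6 genes known for a start site choice set by nucleotides or for attenuation, and it had 4 higher and 1 lower, and the list did not pass (median 0.82, adjusted p = 0.0837) except without wild type replicate 1 (adjusted p = 0.0153). The guanylate median was 2.97 on day A and 1.72 on day B, the purine median was 1.81 and 1.86, and the pyrimidine median was 1.06 and 0.84.

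RPO21 itself (YDL140C, R64 build, chromosome IV, 205360 to 210561) was at -0.31 ± 0.20 and did not pass (adjusted p = 0.226). Of the 12 genes on the list of RNA polymerase II subunits, 10 rose (median 0.73, adjusted p = 0.000522, and adjusted p = 0.475 with an estimated correlation), RPB10 by 1.73 ± 0.22, with list medians of 0.67 on day A and 0.83 on day B. Of 19 RNA polymerase I and III subunit genes 18 rose (median 1.04, adjusted p = 2.66e-07, and adjusted p = 0.475 with an estimated correlation), with RPA135 at least 4.91-fold higher and list medians of 0.87 on day A and 1.22 on day B. Among 27 elongation factor genes 11 rose and 1 fell (10 and 0 adjusted over the list alone), SPT4 by 0.70 ± 0.12 (list median 0.22, adjusted p = 0.00665, and adjusted p = 0.575 with an estimated correlation), with 0.15 on day A and 0.26 on day B. DST1, the TFIIS gene, lay near background and is given no fold for the mean. Mediator genes went both ways, with 2 of 25 higher and 5 lower (1 and 3 adjusted over the list alone; median -0.01, adjusted p = 0.892).

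Biosynthetic and cell cycle lists moved as well. Of 39 amino acid synthesis genes 22 rose and 1 fell (median 0.71, adjusted p = 1.73e-06, and adjusted p = 0.475 with an estimated correlation), TRP5 by 1.42 ± 0.10. The median was 0.38 on day A and 1.15 on day B, and the list level was 9.72 on wild type replicate 1 and 9.17 on replicate 2. Of 25 ergosterol genes 20 rose and 2 fell (median 0.78, adjusted p = 2.58e-06, and adjusted p = 0.475 with an estimated correlation), ERG3 by 2.07 ± 0.16, with list medians of 0.73 on day A and 0.71 on day B. Of 27 G1/S genes 23 rose (median 0.78, adjusted p = 3.06e-08, and adjusted p = 0.475 with an estimated correlation), with RNR1, the ribonucleotide reductase large subunit, at least 4.83-fold higher, and list medians of 0.75 on day A and 0.74 on day B. Histone genes had 4 of 10 higher (median 0.28, adjusted p = 0.0157, and adjusted p = 0.577 with an estimated correlation), HHF2 by 1.02 ± 0.12, with list medians of 0.43 on day A and 0.16 on day B, and without wild type replicate 1 the list lost its call (adjusted p = 0.225). Proteasome genes had 9 of 34 higher and 2 lower (7 and 2 adjusted over the list alone; median 0.28, adjusted p = 0.0343, and adjusted p = 0.7 with an estimated correlation), RPN7 by 0.61 ± 0.10, with list medians of 0.26 on day A and 0.27 on day B. The proteasome list lost its call with a replicate block (adjusted p = 0.0508), without wild type replicate 2 (adjusted p = 0.112), without rpb1-E1103G replicate 1 (adjusted p = 0.0631) and without rpb1-E1230K replicate 1 (adjusted p = 0.0924). Subtelomeric families had 19 of 58 lower and 1 higher (17 and 0 adjusted over the list alone; median -0.25, adjusted p = 0.00237, and adjusted p = 0.58 with an estimated correlation), DAN4 at -0.91 ± 0.11, with list medians of -0.16 on day A and -0.29 on day B. Markers of MATa cells, the mating type of pheromone a-factor, had 5 of 7 lower (median -0.72, adjusted p = 0.0142, and adjusted p = 0.475 with an estimated correlation), AGA2 at -1.11 ± 0.19, with list medians of -0.73 on day A and -0.69 on day B. Without wild type replicate 2 the subtelomeric list (adjusted p = 0.0671) and the MATa list (adjusted p = 0.0606) lost their calls. The 4 MATalpha markers, which would mark cells of the other mating type, were not changed past the test and stayed below background, apart from SAG1, which allowed no bound.

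Other lists did not pass for the mean of the mutants. Glycolysis had 5 of 16 genes higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.103), with HXK2, hexokinase, at 2.93 ± 0.39. Hexose transporters split 4 higher to 4 lower of 13 (adjusted p = 0.892), with HXT3 at 3.22 ± 0.49 and HXT5 at -3.59 ± 0.75 (above background on 1 of 12 mutant arrays), and these transporters are close copies. Phosphate genes had 1 of 16 higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.694), and methionine and sulphur genes 4 of 22 higher and 3 lower (4 and 2 adjusted over the list alone; adjusted p = 0.694). Iron genes had 3 of 18 higher and 5 lower (adjusted p = 0.496), galactose genes 4 of 7 lower (adjusted p = 0.0616), and pheromone response genes 1 of 21 higher and 3 lower (1 and 2 adjusted over the list alone; adjusted p = 0.488). DNA damage genes had 1 of 15 higher and 3 lower (adjusted p = 0.686), and G2/M genes 7 of 15 higher and 1 lower (adjusted p = 0.108). Cell wall genes had 5 of 20 higher and 4 lower (adjusted p = 0.713), drug resistance genes 2 of 13 higher and 4 lower (adjusted p = 0.301), and oxidative stress genes 3 of 16 higher and 8 lower (3 and 9 adjusted over the list alone; adjusted p = 0.135). Nitrogen catabolite repression genes had 1 of 25 higher and 9 lower (adjusted p = 0.108), and no meiosis gene of 22 passed limma's test (adjusted p = 0.729 by camera). Among 7 auxotrophic markers (adjusted p = 0.103) ADE2 rose by 2.16 ± 0.21 and HIS3 was at least 2.38-fold higher, URA3 was at 0.03 ± 0.12, and LEU2, LYS2, TRP1 and MET17 were below background. The 585 longest genes had 104 higher and 168 lower (103 and 167 adjusted over the list alone; adjusted p = 0.129), and the 585 shortest 119 higher and 154 lower (118 and 154 adjusted over the list alone; adjusted p = 0.892). Glycolysis passed without wild type replicate 2 (adjusted p = 0.000778), and galactose genes without wild type replicate 1 (adjusted p = 0.0468), rpb1-N488D replicate 1 (adjusted p = 0.0269) or rpb1-E1103G replicate 2 (adjusted p = 0.0466).

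In all, 3059 genes passed for the mean of the 6 mutants, 1457 higher and 1602 lower, and 3377 had an unadjusted p under 0.05. Over the 7 comparisons with wild type, 141 of 280 list tests passed with the preset correlation, 88 higher and 53 lower, 146 passed by fry, and 0 passed by camera with an estimated correlation. Fry did not call the same lists: over these comparisons and the 2 named pairs of mutants it lost 48 calls and gained 33. Each mutant was compared with the same 2 wild-type arrays, so the 7 comparisons are not independent.

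**Figure D1:**
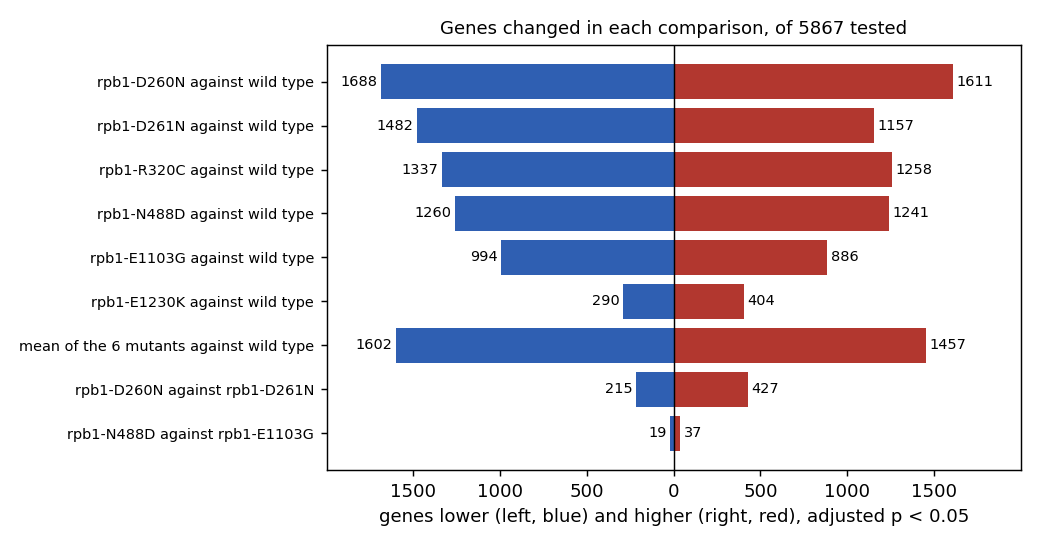
Number of genes past an adjusted p of 0.05 in each comparison, lower on the left (blue) and higher on the right (red), of 5867 tested. Against wild type the count ran from 3299 in rpb1-D260N to 694 in rpb1-E1230K, and rpb1-N488D differed from rpb1-E1103G in 56 genes.

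**Figure D2:**
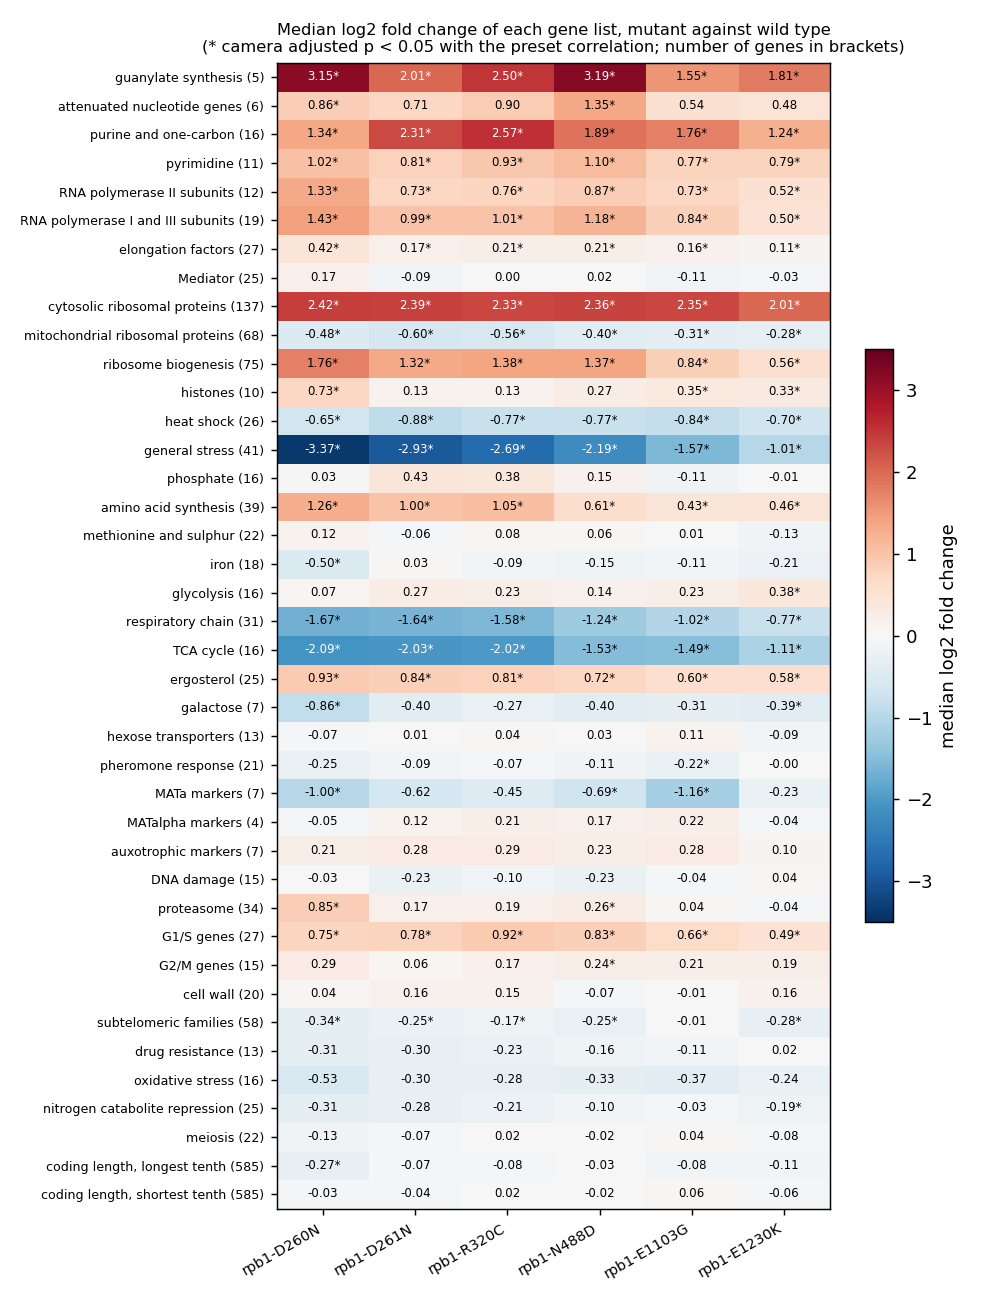
Median log2 fold change of each gene list reported here in each mutant against wild type; colour and number give the median, an asterisk marks a camera adjusted p under 0.05 with the preset correlation, and brackets give the number of genes measured. The cytosolic ribosomal protein median lay between 2.01 and 2.42 in every mutant, and the general stress median ran from -3.37 in rpb1-D260N to -1.01 in rpb1-E1230K.

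**Figure D3:**
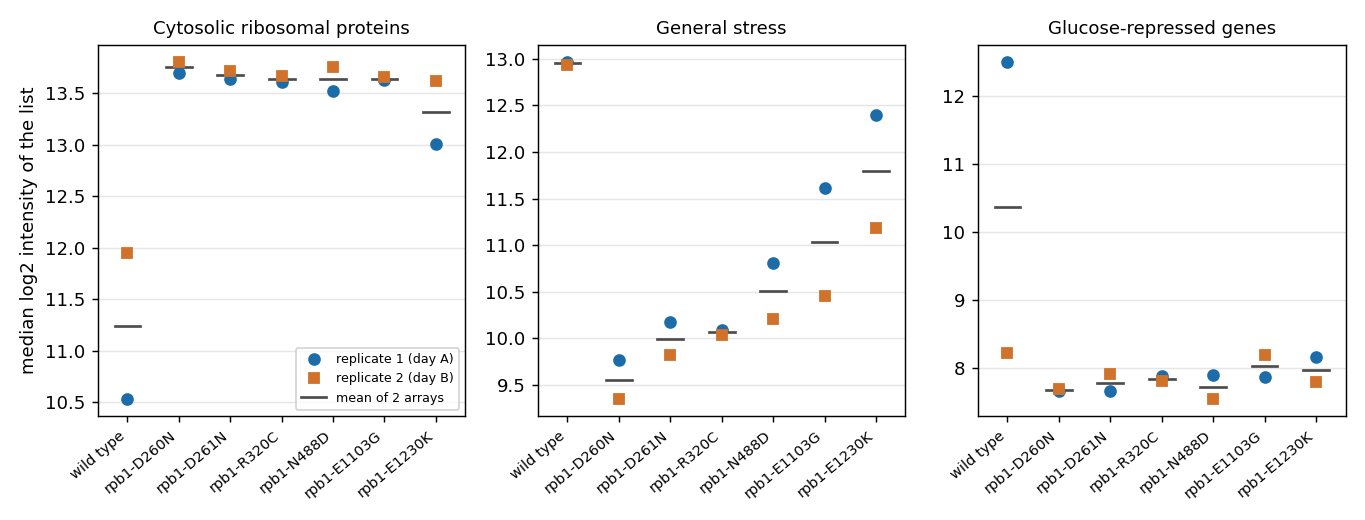
Median log2 intensity of the cytosolic ribosomal protein, general stress and glucose-repressed lists on each array (circles, replicate 1 of day A; squares, replicate 2 of day B; lines, mean of 2 arrays). The wild-type arrays lie below all mutant arrays for ribosomal proteins, and wild type replicate 1 stands at 12.51 for the glucose-repressed genes, a list chosen after the data were seen.

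The comparison of rpb1-D260N with wild type asked what this allele changes in rich medium. IMD2 was among the largest increases, at 4.21 ± 0.40 (adjusted p = 5.98e-05), together with its near-identical copy YAR073W at 4.04 ± 0.38, HXT3, a glucose transporter, at 4.30 ± 0.64, and IMD4, at least 13-fold higher (adjusted p = 6.06e-05). GPH1, glycogen phosphorylase, was at least 20.2-fold lower (adjusted p = 0.000119), ACH1 at least 29.2-fold lower, and DDR2, a stress gene, fell by 4.83 ± 0.59. Of 34 proteasome genes 25 rose and 2 fell (median 0.85, adjusted p = 1.29e-06, and adjusted p = 0.469 with an estimated correlation), PRE6 by 1.23 ± 0.12 and PRE1 by 1.54 ± 0.17, with 0.81 on day A and 0.88 on day B. Of 18 iron genes 10 fell and 1 rose (median -0.50, adjusted p = 0.022, and adjusted p = 0.469 with an estimated correlation), with the cell wall mannoprotein gene FIT3 at -1.96 ± 0.37, and -0.46 on day A and -0.60 on day B, and without wild type replicate 1 the list lost its call (adjusted p = 0.053). The attenuated nucleotide genes had 4 of 6 higher and 1 lower (median 0.86, adjusted p = 0.0451, and adjusted p = 0.469 with an estimated correlation), and lost their call with a replicate block (adjusted p = 0.0568), without wild type replicate 2 (adjusted p = 0.057) and without rpb1-E1103G replicate 1 or 2 (adjusted p = 0.0528). Histones had 8 of 10 higher (median 0.73, adjusted p = 0.00286, and adjusted p = 0.469 with an estimated correlation), HHF2 by 1.63 ± 0.16. General stress had 39 of 41 lower and 1 higher (40 and 1 adjusted over the list alone), with a median of -3.37, -3.08 on day A and -3.53 on day B (adjusted p = 1.98e-12, and adjusted p = 0.469 with an estimated correlation). Among ribosomal protein genes 135 of 137 rose (median 2.42), with 3.15 on day A and 1.88 on day B. DST1 was at least 1.41-fold higher (adjusted p = 0.000161).

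Long genes were lower in rpb1-D260N. Of the 585 longest, 242 fell and 83 rose (median -0.27, adjusted p = 0.000421, and adjusted p = 0.469 with an estimated correlation), with -0.24 on day A and -0.31 on day B. The day B array also stood apart in its slope of intensity with probe position within the gene (0.221, against 0.00684 for the day A array), and without it the median was -0.22 (adjusted p = 0.00372). With each array's length trend removed and a replicate block, the median turned to 0.04. Those 585 genes hold 42 Ty open reading frames. Without them, an exclusion chosen after the data were seen, 201 of 543 fell and 83 rose (median -0.22, adjusted p = 0.00521, and adjusted p = 0.469 with an estimated correlation). Of all 85 Ty open reading frames, which belong to retrotransposons and are close copies of one another, 79 were lower (median -1.71, adjusted p = 1.37e-18, and adjusted p = 0.473 with an estimated correlation), a list chosen after the data were seen. RPO21 was at -0.51 ± 0.27 and did not pass (adjusted p = 0.13). In total 3299 genes passed, 1611 higher and 1688 lower, and 3563 had an unadjusted p under 0.05. With the authors' gene values the split was 826 higher and 518 lower.

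The comparison of rpb1-D261N with wild type asked the same of the neighbouring residue. Purine synthesis stood out among the increases: 15 of 16 purine and one-carbon genes rose and 1 fell (median 2.31, adjusted p = 8.54e-09, and adjusted p = 0.448 with an estimated correlation), with 2.40 on day A and 2.29 on day B. ADE17 rose by 3.93 ± 0.63 (adjusted p = 0.000943), ADE57 by 3.27 ± 0.33 and GUA1 by 3.32 ± 0.35. HXT3 rose by 4.00 ± 0.64, and PHO3, a constitutive acid phosphatase, was at least 8.43-fold higher (adjusted p = 0.000333). IMD2 rose by 1.64 ± 0.40 (adjusted p = 0.00702), and without rpb1-D261N replicate 2 it did not pass (adjusted p = 0.0548). Among decreases CTT1 was at least 13.9-fold lower, the mitochondrial outer membrane gene OM45 at least 8.93-fold lower, and all 31 respiratory chain genes fell (median -1.64, adjusted p = 1.93e-11, and adjusted p = 0.448 with an estimated correlation), with -2.31 on day A and -1.10 on day B. Cytosolic ribosomal proteins had 135 of 137 higher (136 adjusted over the list alone; median 2.39), with 3.06 on day A and 1.70 on day B. Proteasome genes had 2 of 34 higher and 2 lower (1 and 2 adjusted over the list alone; adjusted p = 0.309). RPO21 was at -0.19 ± 0.27 (adjusted p = 0.601). In total 2639 genes passed, 1157 higher and 1482 lower, with 3060 at an unadjusted p under 0.05, and 1748 passed without rpb1-D261N replicate 2. With the authors' gene values 487 were higher and 292 lower.

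The comparison of rpb1-R320C with wild type asked what a change outside those aspartates does. ADE17 rose by 4.04 ± 0.63 (adjusted p = 0.000904), ADE57 by 3.45 ± 0.33 and SHM2, cytosolic serine hydroxymethyltransferase, by 3.42 ± 0.41. Of 16 purine and one-carbon genes 15 rose and 1 fell (median 2.57, adjusted p = 6.82e-09, and adjusted p = 0.474 with an estimated correlation), with 2.80 on day A and 2.34 on day B. GLN1, glutamine synthetase, rose by 3.32 ± 0.52, and IMD2 by 2.50 ± 0.40 (adjusted p = 0.000922). JEN1 was at least 14.7-fold lower, the mitochondrial pyruvate carrier gene MPC3 at least 12.3-fold lower, and all 31 respiratory chain genes fell (median -1.58, adjusted p = 4.08e-12, and adjusted p = 0.474 with an estimated correlation). Subtelomeric families had 23 of 58 lower (median -0.17, adjusted p = 0.00201, and adjusted p = 0.602 with an estimated correlation), with COS8 at -1.11 ± 0.19, and without wild type replicate 2 the list lost its call (adjusted p = 0.0614). RPO21 was at -0.15 ± 0.27 (adjusted p = 0.681). In total 2595 genes passed, 1258 higher and 1337 lower, with 3026 at an unadjusted p under 0.05, and 1696 passed without rpb1-R320C replicate 1. With the authors' gene values 474 were higher and 330 lower.

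The comparison of rpb1-N488D with wild type concerned an allele known as a slow polymerase. IMD2 led the increases at 4.25 ± 0.40 (adjusted p = 0.000275), with YAR073W at 4.11 ± 0.38 and IMD4 at least 13.7-fold higher. All 5 guanylate genes rose (median 3.19, adjusted p = 9.67e-05, and adjusted p = 0.471 with an estimated correlation), with 3.55 on day A and 3.13 on day B. The attenuated nucleotide genes had 4 of 6 higher (median 1.35, adjusted p = 0.0125, and adjusted p = 0.471 with an estimated correlation), URA2 by 2.36 ± 0.18 and ADE12 by 2.07 ± 0.20. CTT1, cytosolic catalase, was at least 13.5-fold lower and FMP16 was at least 19.4-fold lower. G2/M genes had 6 of 15 higher and 1 lower (median 0.24, adjusted p = 0.0272, and adjusted p = 0.529 with an estimated correlation), and lost that call without wild type replicate 1 (adjusted p = 0.153) and without rpb1-N488D replicate 2 (adjusted p = 0.0779). STE4 kept a positive change except with the authors' normalized probes, where it was -0.05. RPO21 was at -0.10 ± 0.27 (adjusted p = 0.797). In total 2501 genes passed, 1241 higher and 1260 lower, with 2976 at an unadjusted p under 0.05, and 1288 passed without rpb1-N488D replicate 2. With the authors' gene values and a replicate block 739 were higher and 1376 lower, and with their normalized probes and a block 735 and 1399.

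The comparison of rpb1-E1103G with wild type concerned an allele known as a fast polymerase. ADE17 rose by 3.74 ± 0.63 (adjusted p = 0.00233), YEF3, a fungal translation elongation factor, by 3.23 ± 0.53, and HXK2, hexokinase, by 3.08 ± 0.50. IMD2 was at 0.78 ± 0.40 and did not pass (adjusted p = 0.156), while IMD3 rose by 1.55 ± 0.35 (without rpb1-E1103G replicate 2 it did not pass, adjusted p = 0.067) and IMD4 was at least 4.04-fold higher. FMP16 fell by 4.23 ± 0.46, JEN1 was at least 14-fold lower and TKL2, a minor transketolase, at least 8.97-fold lower. All 7 MATa markers fell (median -1.16, adjusted p = 8.46e-05, and adjusted p = 0.537 with an estimated correlation), with -1.18 on each day. Among them AGA2, an a-agglutinin subunit, fell by 1.81 ± 0.25 and STE2, the alpha-factor receptor, by 1.16 ± 0.16. Ty open reading frames had 39 of 85 lower (median -0.74, adjusted p = 3.58e-12, and adjusted p = 0.495 with an estimated correlation), a list chosen after the data were seen. RPO21 was at -0.49 ± 0.27 (adjusted p = 0.181). In total 1880 genes passed, 886 higher and 994 lower, with 2559 at an unadjusted p under 0.05. The count was 1178 without wild type replicate 1, 835 without rpb1-E1103G replicate 2 and 686 with only these strains in the fit, and with the authors' gene values 275 were higher and 126 lower.

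The comparison of rpb1-E1230K with wild type asked what this allele, which gave the fewest genes of the 6, changes. Ribosomal protein genes were among its leading increases, and 125 of 137 rose (135 adjusted over the list alone; median 2.01, adjusted p = 8.83e-64, and adjusted p = 0.499 with an estimated correlation), with 2.43 on day A and 1.61 on day B. RPS9B rose by 2.94 ± 0.43 (adjusted p = 0.00574) and RPS1B by 2.71 ± 0.47. GUA1 rose by 2.02 ± 0.35, and 4 of 5 guanylate genes rose (5 adjusted over the list alone; median 1.81, adjusted p = 3.18e-05, and adjusted p = 0.499 with an estimated correlation). IMD2 was at 1.30 ± 0.40 (adjusted p = 0.0581), and with a replicate block it passed (adjusted p = 0.0263). Only 7 of 75 ribosome biogenesis genes rose (6 adjusted over the list alone; median 0.56, adjusted p = 1.72e-11, and adjusted p = 0.499 with an estimated correlation), with 0.02 on day A and 1.06 on day B. General stress had 5 of 41 lower and 1 higher (11 and 1 adjusted over the list alone; median -1.01, adjusted p = 9.9e-07, and adjusted p = 0.499 with an estimated correlation), with -0.29 on day A and -1.74 on day B. GPP2, glycerol-3-phosphatase, was the gene higher, at 1.70 ± 0.22. JEN1 fell by 3.29 ± 0.80 (adjusted p = 0.0266) and SPG1 was at -2.83 ± 0.48. HXT3 passed with a replicate block at 1.82 (adjusted p = 0.042). RPO21 was at -0.43 ± 0.27 (adjusted p = 0.323). In total 694 genes passed, 404 higher and 290 lower, with 1730 at an unadjusted p under 0.05. Of 40 lists tested, 22 passed by camera with the preset correlation and 6 by fry.

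The rpb1-E1230K count depended on single arrays: 222 without wild type replicate 1, 1058 without wild type replicate 2, 458 without rpb1-D261N replicate 1, 458 without rpb1-D261N replicate 2, 1429 without rpb1-E1230K replicate 1 and 53 without rpb1-E1230K replicate 2. Without that last array RPS9B (adjusted p = 0.0533) and JEN1 (adjusted p = 0.239) did not pass. It was 1094 with a replicate block (548 higher and 546 lower), 360 with median scaling (281 higher and 79 lower) 158 with the authors' gene values (156 higher and 2 lower) and 219 with their normalized probes (186 higher and 33 lower). With only these 2 strains in the fit limma gave 0 genes, with 769 at an unadjusted p under 0.05.

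Neighbouring aspartates of Rpb1 were replaced alike in rpb1-D260N and rpb1-D261N, and their comparison asked whether the position matters. IMD2 was higher in rpb1-D260N by 2.57 ± 0.40 (adjusted p = 0.00401), with YAR073W at 2.39 ± 0.38, the mitochondrial oxaloacetate carrier gene OAC1 at least 4.31-fold higher and BUR6, a subunit of the NC2 transcription regulator, at least 4.19-fold higher. Of 34 proteasome genes 24 were higher (27 adjusted over the list alone; median 0.69, adjusted p = 8.27e-14, and adjusted p = 0.547 with an estimated correlation), PRE1 by 1.30 ± 0.17. Purine and one-carbon genes had 7 of 16 lower (8 adjusted over the list alone; median -1.01, adjusted p = 1.02e-06, and adjusted p = 0.684 with an estimated correlation), ADE13 by 1.76 ± 0.27. Iron genes had 8 of 18 lower (9 adjusted over the list alone; median -0.44, adjusted p = 6.68e-07, and adjusted p = 0.178 with an estimated correlation), with the siderophore transporter gene ENB1 at least 2.89-fold lower. Histones had 3 of 10 higher (6 adjusted over the list alone; median 0.61, adjusted p = 0.00221, and adjusted p = 0.684 with an estimated correlation), HHT1 by 0.70 ± 0.13. The largest decreases were Ty open reading frames: YGR027W-A was at least 15.2-fold lower (adjusted p = 0.000438) and YPR158C-C at least 10.9-fold lower (adjusted p = 0.00101). Cytosolic ribosomal proteins had 1 of 137 lower, RPS22B at -2.26 ± 0.30, and a median of 0.08 (adjusted p = 0.705).

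Of the 585 longest genes 56 were lower and 2 higher between rpb1-D260N and rpb1-D261N (54 and 2 adjusted over the list alone; median -0.18, adjusted p = 1.1e-12, and adjusted p = 0.267 with an estimated correlation). The median was -0.125 without rpb1-D260N replicate 2, the array with a probe position slope of 0.221, and -0.22 without rpb1-D260N replicate 1. Without the 42 Ty open reading frames of this list, an exclusion chosen after the data were seen, 24 of 543 were lower and 2 higher (median -0.15, adjusted p = 1.41e-08, and adjusted p = 0.412 with an estimated correlation). For ergosterol genes the median was -0.01 and the mean 0.06 (adjusted p = 0.705). In total 642 genes passed, 427 higher and 215 lower, with 1521 at an unadjusted p under 0.05. The count was 83 without rpb1-D260N replicate 2, 68 without rpb1-D261N replicate 1 and 173 without rpb1-D261N replicate 2. IMD2 did not pass without rpb1-D261N replicate 1 (adjusted p = 0.0559). With a replicate block 5 more lists passed: general stress (median -0.28, adjusted p = 0.0485), and Mediator, guanylate, pheromone response and phosphate genes (adjusted p = 0.0499 each). It was 160 higher and 141 lower with median scaling, 549 and 142 with mismatch probes in the quantile normalization, 13 and 42 with the authors' gene values, and 18 and 48 with their normalized probes.

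A slow and a fast polymerase were set against each other in rpb1-N488D and rpb1-E1103G. IMD2 was higher in rpb1-N488D by 3.47 ± 0.40 (adjusted p = 0.00505), and 3 of the 6 attenuated nucleotide genes were higher (median 0.74, adjusted p = 8.22e-06, and adjusted p = 0.0587 with an estimated correlation): IMD2, URA2 at 1.42 ± 0.18 and ADE12 at 1.09 ± 0.20. IMD4 was at 1.76 ± 0.37 and did not pass (adjusted p = 0.0579), and with a replicate block it passed (adjusted p = 0.0326). Pyrimidine genes had 3 of 11 higher (median 0.36, adjusted p = 0.00413, and adjusted p = 0.596 with an estimated correlation). The Ty open reading frames YGR027W-A and YAR010C were higher in rpb1-N488D, by 2.69 ± 0.34 and 2.29 ± 0.26. SER3, which starts serine synthesis, was lower by a log2 change of -2.14 ± 0.35 (adjusted p = 0.0164), YGP1 was at -1.62 ± 0.30, and BNA5, of NAD synthesis, was at least 2.15-fold lower. STE2 was higher by 1.12 ± 0.16 (adjusted p = 0.0104). Subtelomeric families had 2 of 58 lower (13 adjusted over the list alone; median -0.29, adjusted p = 3.81e-13, and adjusted p = 0.545 with an estimated correlation), with the Y' helicase gene YRF1-6, one of many close copies, at -1.17 ± 0.23. Respiratory chain genes passed only with a replicate block (median -0.19, adjusted p = 0.0412). For galactose genes the median was -0.11 and the mean 0.00475 (adjusted p = 0.854).

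Between rpb1-N488D and rpb1-E1103G 56 genes passed, 37 higher and 19 lower, with 704 at an unadjusted p under 0.05. With a replicate block 112 passed, 58 higher and 54 lower, with mismatch probes in the quantile normalization 46 were higher and 14 lower, and with the authors' gene values 5 were higher and 0 lower, and with their normalized probes 13 and 1. The count was 88 without wild type replicate 1, 88 without wild type replicate 2, 28 without rpb1-N488D replicate 1, 1 without rpb1-N488D replicate 2, 0 without rpb1-E1103G replicate 1 (limma) and 16 without rpb1-E1103G replicate 2. IMD2 did not pass without rpb1-N488D replicate 2 (adjusted p = 0.0796) or rpb1-E1103G replicate 1 (adjusted p = 0.066).

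**Figure D4:**
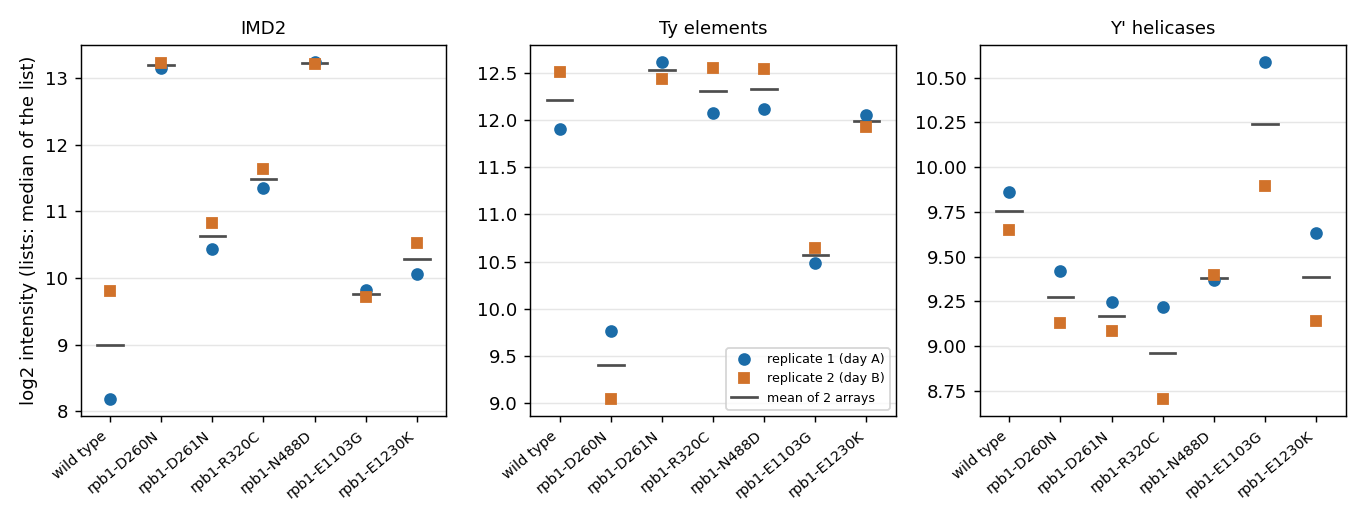
Log2 intensity of IMD2, and median log2 intensity of Ty open reading frames and of Y' helicase genes, on each array (circles, replicate 1 of day A; squares, replicate 2 of day B; lines, mean of 2 arrays). The Ty medians of rpb1-D260N are 9.77 and 9.04 and those of rpb1-E1103G are 10.49 and 10.65, below the 11.91 and 12.51 of wild type; the Ty and Y' lists were chosen after the data were seen.

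The F-test over the differences among the 6 mutants asked which genes depend on the allele. FMP48, a mitochondrial protein kinase gene, had the smallest p (adjusted p = 0.000487), with a mean log2 level of 9.93 in rpb1-E1230K, and was below background in the other 5 mutants. PRM5, induced by cell wall stress, followed (adjusted p = 0.000653), with 10.69 in rpb1-D260N, and was below background in rpb1-E1103G. The other 4 genes named by the rule were Ty open reading frames, among them YPL257W-A with 10.75 in rpb1-D260N, 11.64 in rpb1-E1103G and 13.29 in rpb1-D261N. In total 811 genes passed and 1940 had an unadjusted p under 0.05, and 1336 passed with a replicate block. The count was 321 without rpb1-D260N replicate 1, 123 without rpb1-D260N replicate 2, 292 without rpb1-D261N replicate 1, 313 without rpb1-D261N replicate 2, 367 without rpb1-R320C replicate 1, 383 without rpb1-R320C replicate 2, 396 without rpb1-E1103G replicate 1 and 1542 without rpb1-E1230K replicate 2.

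Other pairs of mutants ranged widely. Between rpb1-D260N and rpb1-E1230K 1677 genes passed (60 in a fit of their 4 arrays alone), between rpb1-D260N and rpb1-E1103G 1139, and between rpb1-E1103G and rpb1-E1230K 7 (limma gave 0 in a fit of their 4 arrays alone, with 223 at an unadjusted p under 0.05). Between rpb1-D261N and rpb1-R320C limma gave 0 genes, with 6 at an unadjusted p under 0.05, and a fit of these 4 arrays alone gave 0 and 81, where chance alone gives 293. The arrays of these 2 strains correlated at 0.993 on day A and 0.998 on day B. Each array of either strain correlated best with an array of the other strain, for example rpb1-D261N replicate 2 at 0.998 with rpb1-R320C replicate 2 and at 0.994 with its own replicate. Whether the RNA of these 2 came from separate strains was not tested, the labels were used as given, and both count among the 6 mutants and the 15 pairs. Limma gave 0 genes also between rpb1-D261N and rpb1-N488D (379 at an unadjusted p under 0.05, 22 passing in a fit of their 4 arrays) and between rpb1-R320C and rpb1-N488D (288 and 43).

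The genes that passed one way in every mutant are those that differed from wild type in all 6. There were 642, 371 higher and 271 lower, where independent lists of these sizes would share 0.15 and 0.17. Because wild type is common to all 6 comparisons, the fold changes of unchanged strains also correlate: the mean correlation of 15 pairs of mutants was 0.926 (0.863 to 0.994), against 0.498 in simulated unchanged strains, which shared 0 genes. One sign in all 6 mutants was held by 68.1% of genes, against 28.5% in simulated unchanged strains. The simulation drew noise for each gene apart, with the same spread in all strains. It held no joint shift of the wild-type cultures. Neither it nor the independent lists can therefore tell such a shift from an effect of the alleles. The count was 981 with a replicate block, 339 with median scaling (263 higher and 76 lower), 155 with the authors' gene values (153 higher and 2 lower) and 207 with their normalized probes (174 higher and 33 lower). It was 213 without wild type replicate 1, 425 without rpb1-D261N replicate 2, 1274 without rpb1-E1230K replicate 1 and 52 without rpb1-E1230K replicate 2. With only the compared strains in each fit limma gave 0, since rpb1-E1230K then had 0 genes.

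A trend with gene length was examined because the series asks which genes are hard to transcribe in such mutants. Over 5847 genes, the slope of log2 level on log2 coding length was -0.14 (SD 0.05, n = 12 arrays) in mutants and -0.11 (SD 0.00365, n = 2 arrays) in wild type. The difference of -0.03 was not larger than chance in an exact two-sided permutation test (p = 0.253, as large in 23 of 91 splits), with -0.03 on day A and -0.04 on day B. Without ribosomal protein and ribosome biogenesis genes it was -0.01 (p = 0.901 in the exact permutation test). The slopes of rpb1-D260N were -0.19 and -0.27, lower than those of all other arrays. The slope of intensity with probe position within the gene was 0.221 on rpb1-D260N replicate 2, the array at -0.27, against 0.00684 on rpb1-D260N replicate 1 and -0.116 to 0.0481 on the arrays of the other strains. Length slope and RNA or target quality were not separated on that array.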

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

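The test of the days against each other and the 3 tests of explanations in this part were chosen after the results were seen.

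The contrast between the mutants and wild type was compared between day A and day B. Each day has 1 wild-type array, so this sets 2 single wild-type arrays against each other, with a spread taken from the mutants alone (5 residual degrees of freedom). The wild-type replicates correlated less with each other (r = 0.943) than those of any mutant, so that spread is too small for them and the p of this fit are not reported. The limma count of 298 genes, 178 with a higher change on day A and 120 with a lower one, therefore describes how far apart these 2 arrays were and does not show that the days differ. Among genes chosen after their values were seen, PCK1, of gluconeogenesis, had a day A minus day B difference of -6.38, FBP1 of -5.82, MLS1 of -5.76 and ICL1, of the glyoxylate cycle, of -4.95. RPP0, a ribosomal stalk gene, stood at 2.92. For the cytosolic ribosomal protein list the median difference was 1.23, and for the glucose-repressed list, chosen because it was high on wild type replicate 1, it was -3.69.

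The pattern weighed here is that ribosomal protein transcripts were higher in all 6 mutants than in wild type, on 6 of 6 day A arrays and 6 of 6 day B arrays. The tables argue against extraction session as its whole cause: with session as a term the median shift was still 2.16, with a standard deviation of 0.484 over the genes. They also argue against quantile normalization, since median scaling gave 2.39. The growth state of the wild-type cultures stays open and cannot be told apart from an effect of the alleles: glucose-repressed genes had a median difference of -2.72, -5.15 on day A and -0.43 on day B, so the wild-type culture of day A may have been close to glucose exhaustion. For the mean of the mutants 9 of these 10 genes fell. ADH2 went the other way, at 0.404 on day A and 0.0751 on day B, and MDH2 was at -1.97 and -1.31. An effect of the alleles, the difference that the design names, also stays open and was not tested.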

How the results depend on the processing

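The alternatives with array weights, with the authors' values and a block, and with doubted arrays left out were chosen after the data were seen. The 11 counts of genes are those for each mutant, the mean of the 6, the pairs rpb1-D260N with rpb1-D261N and rpb1-N488D with rpb1-E1103G, the F-test and all 6 one way. They stayed within 1.5 times their value with no background correction, a normexp offset of 0, mismatch probes in the normalization, the mean of probes, the dimmest 25% left out, and eBayes with trend and robust. For each change below the cause was not tested, except that stricter thresholds call fewer genes by construction.

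With an estimated correlation camera passed 0 lists of 280, against 141 with the preset and 146 by fry, which were not all the same lists. Median scaling gave 339 genes for all 6, 370 for the F-test, 301 for rpb1-D260N with rpb1-D261N, 360 for rpb1-E1230K and 12 for rpb1-N488D with rpb1-E1103G. The authors' gene values gave 155 for all 6, 56 for the F-test, 1232 for the mean, 55 for rpb1-D260N with rpb1-D261N, 1344 for rpb1-D260N, 779 for rpb1-D261N, 804 for rpb1-R320C, 750 for rpb1-N488D, 401 for rpb1-E1103G, 158 for rpb1-E1230K and 5 for rpb1-N488D with rpb1-E1103G. The authors' normalized probes, in the same order, gave 207, 166, 1421, 66, 1567, 968, 1013, 1011, 578, 219 and 14.

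With only the strains compared, all 6 gave 0, rpb1-E1230K 0 (limma, 769 at an unadjusted p under 0.05), rpb1-E1103G 686, rpb1-N488D 1349 and rpb1-D260N with rpb1-D261N 1254. A replicate block gave 981 for all 6, 1336 for the F-test, 1094 for rpb1-E1230K and 112 for rpb1-N488D with rpb1-E1103G, and moved no other of these counts by more than 1.5 times. With the length trend removed as well it gave 965 for all 6, 1070 for rpb1-E1230K and 117 for rpb1-N488D with rpb1-E1103G. Session as a block gave 1125 for rpb1-E1230K and 108 for rpb1-N488D with rpb1-E1103G.

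An adjusted p under 0.01 gave 114 for all 6, 132 for the F-test, 171 for rpb1-D260N with rpb1-D261N, 1673 for rpb1-D261N, 1622 for rpb1-R320C, 1479 for rpb1-N488D, 911 for rpb1-E1103G, 118 for rpb1-E1230K and 16 for rpb1-N488D with rpb1-E1103G. Requiring in addition to an adjusted p under 0.05 an absolute log2 fold change of at least 1 gave 340 for all 6, 1007 for the mean, 193 for rpb1-D260N with rpb1-D261N, 1582 for rpb1-D260N, 1133 for rpb1-D261N, 1140 for rpb1-R320C, 1063 for rpb1-N488D, 816 for rpb1-E1103G and 369 for rpb1-E1230K.

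Array weights gave 231 for all 6 (188 higher and 43 lower), 1505 for the F-test, 1619 for rpb1-D260N with rpb1-D261N and 237 for rpb1-E1230K. The authors' gene values with a block gave 304 for the F-test and 221 for rpb1-D260N with rpb1-D261N, and their normalized probes with a block gave 348, 180, and 33 for rpb1-N488D with rpb1-E1103G. Without the 3 arrays of lowest signal over background (replicate 1 of rpb1-N488D and rpb1-R320C and replicate 2 of rpb1-E1103G) all 6 gave 0, the F-test 21, rpb1-D260N with rpb1-D261N 269, rpb1-R320C 1354, rpb1-E1103G 112, rpb1-E1230K 0 and rpb1-N488D with rpb1-E1103G 0. Without replicate 1 of both wild type and rpb1-E1230K all 6 gave 1053, rpb1-D260N with rpb1-D261N 1067, rpb1-E1230K 1201 and rpb1-N488D with rpb1-E1103G 188.

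Without single arrays the lone array left in a strain was assumed to vary like the others. The counts then ran from 132 to 145 for lists, 52 to 1274 for all 6, 123 to 1542 for the F-test, 2192 to 3138 for the mean, 68 to 755 for rpb1-D260N with rpb1-D261N, 2568 to 3346 for rpb1-D260N, 1748 to 2690 for rpb1-D261N, 1696 to 2644 for rpb1-R320C, 1288 to 2592 for rpb1-N488D, 835 to 2098 for rpb1-E1103G, 53 to 1429 for rpb1-E1230K and 0 to 88 for rpb1-N488D with rpb1-E1103G. The difference in length slope ran from -0.0383 to -0.0222.

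STE4 in rpb1-N488D turned to -0.0478 with the authors' normalized probes, with and without a block. The 585 longest genes in rpb1-D260N turned to 0.0367 with a replicate block and the length trend removed, which by construction takes away such a trend. With a replicate block 1538 results for single genes stayed on their side of the threshold, called or not, 68 gained a call and 1 lost it, and of those for lists 351, 7 and 2. Quantile normalization gives all arrays one distribution, so a median change near 0 over all genes is fixed by construction. It shows nothing about total transcript levels. That median log2 change was 0.000473 in rpb1-R320C, 0.00466 in rpb1-N488D and 0.00117 in rpb1-N488D with rpb1-E1103G. Under median scaling it was 0.127 in rpb1-R320C. It was -0.111, -0.203 and -0.155 with the authors' gene values, and -0.123, -0.214 and -0.158 with their normalized probes. Lists of GC content and introns were not run. Signal over background limits what can be seen: on rpb1-E1103G replicate 2 only 1335 of 5867 genes were above background, so changes of the other genes are compressed or given as bounds.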

Other observations

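Each mutant was also compared with the mean of the other 5 mutants, a comparison chosen after the data were seen. The wild-type arrays do not enter these differences, but they do enter the shared estimate of the spread. Proteasome genes were higher in rpb1-D260N, with 27 of 34 higher and 1 lower (median 0.69, adjusted p = 1.21e-14, and adjusted p = 0.542 with an estimated correlation), and 9 of 18 iron genes were lower (median -0.35, adjusted p = 0.000347, and adjusted p = 0.315 with an estimated correlation). BUR6 was higher there (adjusted p = 0.000203), and since it was above background on only 2 of 10 arrays of the other mutants no size is given. In rpb1-E1230K 24 of 41 general stress genes were higher (median 1.73) and 17 of 75 ribosome biogenesis genes lower (median -0.76), each with an adjusted p = 6.74e-23, and adjusted p = 0.556 with an estimated correlation. The list levels of its replicates lay apart, at 12.40 and 11.18 for general stress and 7.38 and 8.32 for ribosome biogenesis. Replicate 1, which is closer to wild type in both lists, correlated better with wild type replicate 2 (r = 0.976) than with its own replicate (r = 0.960), so much of this difference rests on that array. In rpb1-E1103G the phosphate transporter gene PHO84 was at least 8.32-fold lower (adjusted p = 0.0213), PRM5 at least 2.05-fold lower (adjusted p = 0.00282; above background on 8 of 10 arrays of the other mutants), and 22 of 31 Y' helicase genes, which are close copies, were higher (median 1.08, adjusted p = 8.83e-36, and adjusted p = 0.164 with an estimated correlation).

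In that comparison 1397 genes passed for rpb1-D260N (820 higher and 577 lower), 477 for rpb1-E1230K (269 and 208; 996 with a replicate block) and 106 for rpb1-E1103G (58 and 48; 173 with a replicate block). Limma gave 0 for rpb1-D261N (525 at an unadjusted p under 0.05, 30 with a replicate block), 0 for rpb1-R320C (333 and 44) and 0 for rpb1-N488D (438 and 41).

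The tests of Ty elements and of IMD2 below were chosen after these results were seen. Ty transcripts were low in rpb1-D260N and rpb1-E1103G, with signs that held under every scaling run: against wild type 79 of 85 open reading frames were lower in rpb1-D260N (medians from -1.86 to -1.69 over scalings) and 39 in rpb1-E1103G. Against extraction session speaks the smaller of the day differences between rpb1-D260N and rpb1-D261N, -1.57, with -2.08 on day B. A growth difference from wild type shared by the mutants is argued against as the cause. The other 4 mutants, whose ribosomal protein shifts were 2.01 to 2.39, had a mean Ty shift of -0.0636 (SD 0.15). Among them rpb1-E1230K had a Ty median of -0.261 (camera adjusted p = 0.000778, and adjusted p = 0.642 with an estimated correlation), with 0 of 85 open reading frames past the threshold. A culture state particular to rpb1-D260N or rpb1-E1103G was not tested. Fewer Ty copies in those strains may be the cause and cannot be told apart from less transcript per copy, since 66 open reading frames lower in rpb1-D260N than in rpb1-D261N would follow from either. An effect of the alleles on Ty transcription also stays open, untested.

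IMD2 was highest in rpb1-D260N and rpb1-N488D. Between rpb1-N488D and rpb1-E1103G, signal shared with IMD3 and IMD4 is argued against as the whole cause. There IMD2 differed by 3.47, IMD3 by 1.36 and IMD4 by 1.76, which leaves 1.72 (SE 0.538) beyond the larger of the copies. That SE treats the genes as independent, though they were measured on the same arrays. Against wild type, where IMD4 was below background, IMD2 and IMD4 lay closer together. They were at 4.21 ± 0.40 and 3.70 ± 0.37 in rpb1-D260N and at 4.25 ± 0.40 and 3.77 ± 0.37 in rpb1-N488D. Shared signal was not tested for those changes. In rpb1-D260N, a growth state that shifts the ribosomal protein or general stress lists is argued against as the cause. IMD2 differed by 2.57 (SE 0.395) between rpb1-D260N and rpb1-D261N, whose ribosomal protein and general stress lists differed by 0.08 and -0.28. That comparison cannot exclude a culture state particular to rpb1-D260N, and growth state was not tested for rpb1-N488D. A candidate explanation that stays open, as a hypothesis, is that these alleles alter the choice of start site that attenuates IMD2 when GTP is plentiful, and no test of start sites was run. YAR073W, a near-identical copy, cannot be separated from IMD2 here.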
